A study of Rattus norvegicus and Homo sapiens and Mus musculus with 18 samples.

How the data were processed

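The series holds poly(A)-selected Illumina mRNA libraries from sperm: 6 human (ejaculated), 5 mouse and 7 rat (both by needle puncture of the cauda epididymis). Groups and replicate numbers were taken from the sample titles, and all 18 columns were mapped to a sample. The labels give no treatment, batch, day or pairing. Per the submitters' processing notes, reads were aligned with Bowtie to the genomes hg19, mm10 and rn6. The version of Bowtie, the quantification tool, the annotation release, the source of the gene pairing and any filters are not given in the sources used here.

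The authors deposited 1 table of normalized values with 65535 rows, whose unit, per the deposited values, is TPM, a library's share of transcripts scaled to a fixed total: human columns sum to 1000000. Mouse columns sum to 993092 to 997378 and rat columns to 780114 to 963480 over the rows held. Of the rows, 53785 carry human Ensembl gene IDs, on which the authors placed rodent values too, and 11750 carry mouse IDs, with mouse values alone, which no comparison here uses. Symbols were added from a table of gene names (53393 of the human IDs) and from GENCODE release 29. No coordinates are printed, because the annotation at hand is on another genome build than the authors' human alignment. In all, 423 Y-linked genes, XIST and TSIX were left out of every gene result.

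The form of the values was checked. In every library, the values of a gene are whole multiples of 1 step over a divisor that is the same in all libraries (tolerance 1e-06 of a read). All 39456 rows with at least 6 libraries above 0 met this, against 0 of 2000 control rows whose values had been moved at random by up to 0.1%. Divisors ran from 1 to 16192.5 in steps of 0.5, with a median of 7929 over the genes compared with exon lengths. Each is the smallest divisor that makes the reads whole, and the recovered reads follow from it. They limit the precision of each value, and are given per library in the report. The reads of some genes share a common factor above 1 within a species. Of 9251 tested genes, 7706 have none and 1540 have factors that differ between species, for a reason that is not known.

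Genes were compared if they were above 0 in at least 1 library of each species (16911 genes) and had a mean of at least 1 TPM over all libraries (9251 genes). Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 1 coefficient per species, 2-sided moderated test). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. Changes are printed relative to the change of the median gene, while calls rest on the unshifted values, and SE is limma's standard error. Similar abundance was tested by a pair of one-sided tests against a log2 difference of 1 in every species pair. A gene was detected in a species at 1 TPM or more in every library, and pairs of detection lists were compared by Fisher's exact test. Rank correlations are Spearman's across genes, which are not independent replicates.

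The 23 gene lists (sperm structures, metabolism, protein turnover, mitochondria and markers of other cell types) were fixed before the data were examined, as were the comparisons, thresholds and alternatives that needed no look at the data. Lists were tested with camera at a preset correlation of 0.01, with adjustment over 69 tests, beside camera with an estimated correlation and fry. Genes to name were chosen by a rule fixed at the same time. It took per species pair the 10 largest and 10 most negative changes among called genes without overlap of libraries, and the 20 genes with the highest lowest percentile across the species. It also took the 10 genes of similar abundance with the highest TPM and, per list, the 4 members with the highest TPM and up to 2 called members each way. Uncharacterized loci were left out, and so were olfactory receptors outside the lists. Genes of multigene families (SPINK, ZNF, SSX, KRT, globins, ribosomal proteins, TCP10L) are uncertain, since reads or symbols can be shared between members. From this set the text prints examples, picked after the values were seen and mostly with calls that held with each library left out. Some members of this set are not reported here.

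Alternatives covered the pseudocount, the filter on low means, the scaling, variance weights per species, families with shared reads, other thresholds, and leaving out each library in turn. Those that use recovered reads, common factors or divisors, and the one without rat 22 and rat 24, were chosen after the data were seen. The call of genes was tested on simulated data with 9251 genes. Of 50 genes changed by a log2 of 1.5, 80% were recovered between human and mouse, 64% between human and rat and 64% between mouse and rat. Of 50 changed by a log2 of 2, the shares were 90%, 94% and 94%, and 5, 4 and 4 of 9051 unchanged genes were called. The simulated genes varied independently, with the same normal spread in all species and no shift of whole libraries. The real libraries need not meet these settings, so the shares need not hold for them. Camera called 0 of 200 simulated unchanged lists of independent genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No pair of libraries was a duplicate of the same reads.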

Results

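Poly(A)-selected mRNA was sequenced from sperm of 3 species: ejaculated human sperm (6 libraries) and sperm taken from the cauda epididymis of mice (5 libraries) and rats (7 libraries). The series asked which sperm transcripts are alike across the species, for use as markers of male reproductive toxicity in animals. Every library was a separate labelled sample, but the labels do not say whether any was pooled or a repeat of another, so n counts libraries. The p-values of single genes below measure only the spread between these samples. Those of camera set a list against all other genes, which the preset correlation takes as nearly independent. Species could not be separated from ejaculated against epididymal sperm, or from the genome each library was aligned to.

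The deposited table gave TPM values without read totals. Each gene's values had the form of whole reads over 1 divisor shared by all libraries, so reads could be recovered. They came to 1603092 to 2264225 reads per human library, 3679201 to 10004350 per mouse library and 1277150 to 6523113 per rat library. The divisors had no relation to annotated exon length across 18282 genes (Spearman rho 0.00880, genes not being independent replicates). TPM levels of different genes were therefore not on 1 scale. In the ratio of the TPM of 1 gene between libraries, the gene's own divisor cancels. The ratio still depends on the divisors of all genes, through the total that each library is scaled to. It could also depend on the common factors of the gene's reads, which differed between species in 1540 of 9251 tested genes. The log2 changes below are of TPM + 1, and the added 1 shrinks the changes of genes with low TPM. Their sizes, the order of genes by change and the medians of lists therefore depend on the divisors too. The 242 genes with divisors up to 10 held 67.3% to 89.2% of a library's TPM, and so set most of its scale. SRRM2, which encodes a nuclear speckle protein, alone held 5.35% to 10.2% in human, 20.9% to 63.0% in mouse and 3.59% to 12.6% in rat libraries.

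**Figure D1:**
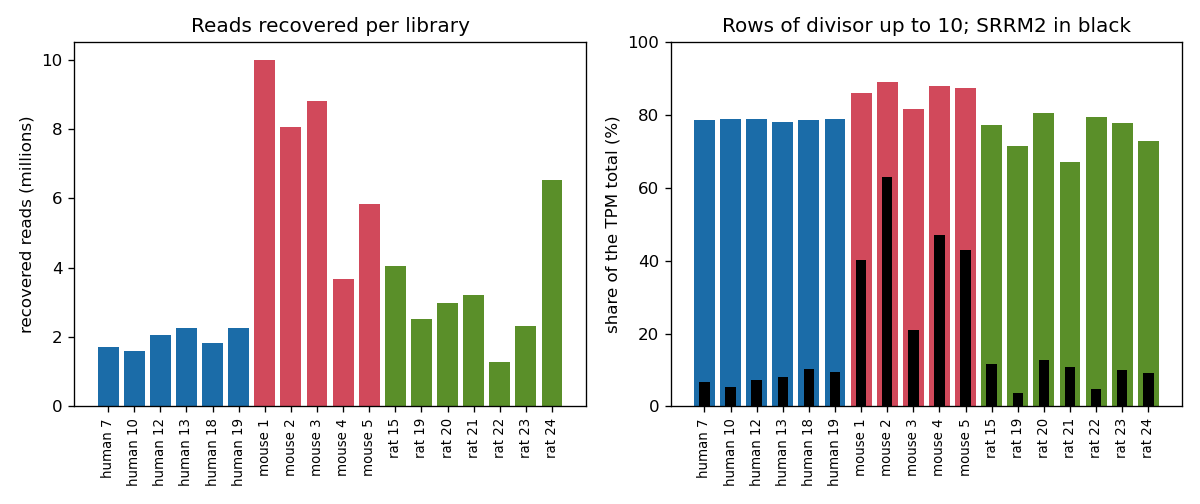
Recovered reads per library (left) and the share of each library's TPM, in percent, held by genes with divisors up to 10 (right, with SRRM2 alone in black), one bar per library. Mouse libraries held 3679201 to 10004350 reads and human libraries 1603092 to 2264225, and SRRM2 took its highest shares in mouse libraries, 20.9% to 63.0%.

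**Figure D2:**
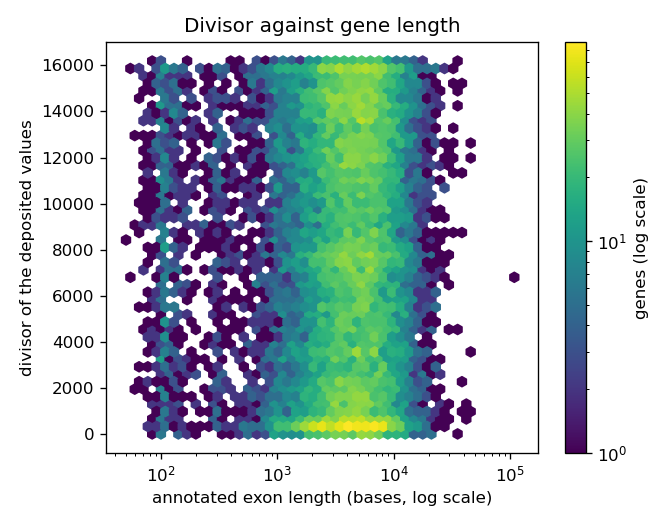
Divisor of the deposited values against annotated exon length in bases on a log scale, with the color giving the number of genes per hexagon on a log scale. The Spearman rho was 0.00880 across 18282 genes, chosen with a minimum of recovered reads that was not applied to the genes drawn.

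The question behind the series, which transcripts sperm of the 3 species share, was first addressed by detection. At a minimum of 1 TPM in every library of a species, 10699 genes were detected in human sperm, 4855 in mouse sperm and 4115 in rat sperm. Of the 16911 genes measured in all 3 species, 6912, 4233 and 3942 were detected, and 2133 were detected in all 3, against 403 for independent lists. Mouse and rat shared 2699 of them (odds ratio 16.2), human and mouse 2989 (odds ratio 5.36) and human and rat 2835 (odds ratio 5.59). Divisors shared across species enter these odds ratios. With at least 10 recovered reads in every library as the criterion, which detects more genes and is easily met by a gene with a large common factor, 7508 genes were shared, against 5408 for independent lists. The odds ratios were then 8.14 for mouse and rat, 3.89 for human and mouse and 3.14 for human and rat. The table stops at 65535 rows, none of them with rat gene IDs, and rat columns sum to 780114 to 963480 TPM. The detected rodent genes are therefore those of the rows held, and their number is not comparable with the human one.

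The transcripts with the highest TPM percentile in all 3 species were SRRM2, FADS2, EXD1, SLFN5, UBL5, SPRYD3, EMX2, UPF3A, POLR3D, TMEM80, TSC22D4, MAGED1, TBL1X, MLF1, USP15, ARHGEF37, PWWP2A, KLF17, MVB12B and PLA2G4F. FADS2, a fatty acid desaturase, stood at 18076 ± 8246 TPM in human (mean ± SD, n = 6), 15488 ± 8939.9 in mouse (n = 5) and 17062 ± 7556 in rat (n = 7). All 20 of these genes had a divisor of 1, so their rank rested on the divisor. FADS2 had 56 to 165 reads per human library. The lowest percentile of the 20 on the scale of recovered reads ranged from 29.9 to 98.2. Genes were also ranked by recovered reads, an alternative chosen after the data were seen. PRM2, which encodes a protamine that packs sperm DNA, then stood near the top in all 3 species, with 546 to 2960 reads per human, 5404 to 11060 per mouse and 111 to 2312 per rat library. So did the mitochondrial genes MT-ND5, MT-ND6, MT-ND4, MT-CYB and MT-ATP6. Others were the glycolytic gene ENO1, PABPC1, which encodes a poly(A)-binding protein, EIF5B, which encodes a translation initiation factor, and the ribosomal protein gene RPL29. Values of ENO1, PABPC1 and RPL29 were whole multiples of more than 1 read in every species (RPL29: 60 in human, 20 in mouse, 3 in rat), so their read totals were uncertain.

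Abundance ranks were compared across genes by Spearman's rho between species means. The rho was 0.721 between mouse and rat, 0.570 between human and rat and 0.558 between human and mouse. Between single libraries it was 0.863 to 0.959 within human, 0.833 to 0.954 within mouse and 0.597 to 0.939 within rat. Across species it was 0.519 to 0.724 between mouse and rat, 0.461 to 0.577 between human and mouse and 0.411 to 0.600 between human and rat. Part of the rho between species means came from the shared divisors. On recovered reads it fell to 0.601 between mouse and rat, 0.336 between human and rat and 0.365 between human and mouse, so the order of the human pairs turned.

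Similar abundance was tested directly, with the species required to lie within a log2 difference of 1 of each other in every pair. Of 9251 genes tested, 52 passed. Among those with the highest TPM, an order that rests on the divisors, were NUP153, which encodes a nuclear pore protein, SLC35B1, a nucleotide sugar transporter gene, and ALDH3A2, a fatty aldehyde dehydrogenase gene. They were followed by ATP9A, GPATCH8, JPT2, TNPO3, which encodes a nuclear import receptor, HECA and COQ2, an enzyme gene of coenzyme Q synthesis. NUP153 stood at 2.57 ± 0.406 TPM in human, 3.0 ± 1.47 in mouse and 2.48 ± 0.47 in rat (mean ± SD, n = 6, 5 and 7). Its limma adjusted p for equivalence was 0.0423, and ATP9A had adjusted p = 0.020. Each of these 9 genes missed the threshold when 1 of at least 4 of the libraries was left out. Examples are NUP153 with adjusted p = 0.0998 without mouse 1 and ATP9A with adjusted p = 0.0602 without mouse 5. The count itself depended on single libraries. It was 30 without human 7, 24 without human 12, 27 without human 13, 21 without human 18 and 23 without human 19. Among the rodents it was 22 without mouse 1, 27 without mouse 2, 25 without mouse 4, 15 without mouse 5, 93 without rat 21, 254 without rat 22, 26 without rat 23 and 92 without rat 24. It was 374 after median-of-ratios scaling and 423 after quantile normalization, but 1 with the same total over the paired genes. By limma it was 0 with a pseudocount of 0.1 (180 at an unadjusted p under 0.05), with a mean of at least 5 TPM (76) and on recovered reads (235). The added 1 shrinks differences at low TPM, so passing rested in part on low levels and does not show equal TPM.

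Of the 18 epididymal markers tested, 12 were lower and 2 higher in human than in mouse sperm, while of 35 axoneme genes 22 were higher and 1 lower. SPINK8, which encodes a Kazal-type protease inhibitor, stood at 3.55 ± 3.04 TPM in human sperm (mean ± SD, n = 6) and 5850.2 ± 6476 in mouse sperm (n = 5), a log2 change of -10.59 (SE 0.78). CD52, a glycoprotein gene of the epididymis and of lymphocytes, stood at 11.4 ± 2.76 and 2829.8 ± 2626 TPM, and GPX3, a secreted glutathione peroxidase gene, at 0.259 ± 0.247 and 152 ± 130.0. Of the mouse libraries mouse 3 held the most of each, and without it the mouse means were 3001, 1689 and 95.3 TPM. Without human 7 the human mean of GPX3 was 0.167 TPM. Of the 42 cytosolic ribosomal protein genes tested, 41 were lower in human. The median gene was 0.50 higher in human on the log2 scale, and changes are given relative to it.

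Beyond SPINK8, the genes lowest in human were CRISP3 at -9.42 (SE 1.21), a cysteine-rich secretory protein gene, NDUFA3 at -9.35 (SE 0.70), a gene of respiratory complex I, and LENG8 at -9.23 (SE 1.12). Then came PTGDS at -8.77 (SE 1.13), the gene of prostaglandin D synthase, CD52 at -7.94 (SE 1.11), and LDHD at -7.73 (SE 0.48), a D-lactate dehydrogenase gene, and after them CEACAM21 at -7.28 (SE 1.14), GPX3 at -7.12 (SE 0.50) and HOXB4 at -7.04 (SE 0.47), a homeobox gene. Human libraries held few reads of most of them, 0 to 5 of SPINK8, 0 to 2 of PTGDS and 0 to 4 of LENG8, whose divisor was 1. Human values of CEACAM21 were whole multiples of 286 reads against 13 in mouse. The genes highest in human were TAAR5 at 6.52 (SE 1.79), a trace amine receptor gene, SYCP3 at 6.43 (SE 0.55), a gene of the synaptonemal complex, PRRT2 at 6.40 (SE 0.46), a synaptic protein gene, and FPR1 at 5.96 (SE 0.56), the formyl peptide receptor gene of phagocytes. They were followed by BTN2A2 at 5.74 (SE 0.47), a butyrophilin gene, the U1 pseudogene RNU1-33P at 5.70 (SE 0.63) and SSX3 at 5.58 (SE 0.40), a cancer-testis antigen gene. The last of the 10 were NELL2 at 5.54 (SE 0.47), ISLR2 at 5.53 (SE 0.45) and C18orf25 at 5.52 (SE 0.35). TAAR5 stood at 18094 ± 4554 TPM in human and 178 ± 154 in mouse (114 without mouse 4), from 57 to 132 and 2 to 8 reads per library. SYCP3 values were whole multiples of 107 reads in human and of 1 in mouse, a ratio of 6.74 on the log2 scale that nearly equals its change, and SSX3 had a ratio of 4.81.

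By group, cytosolic ribosomal protein genes had a median log2 change of -3.23 (adjusted p = 4.58e-20 by camera, adjusted p = 0.594 with an estimated correlation). RPS6 was at -6.22 (SE 0.54), RPSA at -5.54 (SE 0.71) and RPS15 at -5.15 (SE 0.42). RPL13A, at 1.70 (SE 0.32), was the 1 member higher in human, with values in multiples of 6 reads in human and 2 in mouse. Among epididymal epithelium markers 2 of 18 tested members were higher and 12 lower (2 and 13 adjusted over the list alone), with a median of -3.47 (adjusted p = 1.20e-05 by camera, adjusted p = 0.594 with an estimated correlation). The carboxylesterase gene CES5A was at -6.09 (SE 0.76), the lipocalin gene LCN12 at -4.87 (SE 0.41) and the clusterin gene CLU at -3.79 (SE 0.44), while CUBN, the cubilin gene, was higher at 3.52 (SE 0.56). For nuclear-encoded oxidative phosphorylation 4 of 37 tested members were higher and 20 lower (median -1.70, adjusted p = 1.52e-05 by camera, adjusted p = 0.77 with an estimated correlation). NDUFV2 was at -5.71 (SE 0.68) and COX8A at -5.57 (SE 0.68), while SDHC was higher at 1.40 (SE 0.26). For mitochondrially encoded proteins 1 of 13 tested members were higher and 5 lower (median -1.81, adjusted p = 0.0274 by camera, adjusted p = 0.77 with an estimated correlation). MT-CO1 was at -6.10 (SE 1.01) and MT-ND1 at -6.0 (SE 0.88). Without mouse 3 the list missed the threshold (adjusted p = 0.0567). Of the proteasome and ubiquitin list, 2 of 28 tested members were higher and 8 lower (median -0.90, adjusted p = 0.00861 by camera, adjusted p = 0.77 with an estimated correlation). PSMB6 at -3.17 (SE 0.34) and PSMA7 at -2.10 (SE 0.23) were the lowest. Of the housekeeping genes, 0 of 12 tested members were higher and 4 lower (median -1.02, adjusted p = 0.0173 by camera, adjusted p = 0.77 with an estimated correlation). B2M was at -6.52 (SE 0.88), EEF2 at -5.32 (SE 0.64) and ACTB at -1.81 (SE 0.31).

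Sperm structure divided. Of the axoneme genes, 22 of 35 tested members were higher and 1 lower (median 0.73, adjusted p = 0.00861 by camera, adjusted p = 0.77 with an estimated correlation). The dynein heavy chain gene DNAH12 stood at 13 ± 2.23 TPM in human and 0.313 ± 0.246 in mouse (2.91, SE 0.29). CFAP52 was at 2.40 (SE 0.44) and DNAH3 at 1.90 (SE 0.22), and MEIG1 was lower at -2.39 (SE 0.29). Of the outer dense fibre and fibrous sheath genes, 2 of 17 tested members were higher and 9 lower (median -1.60, adjusted p = 0.00158 by camera, adjusted p = 0.77 with an estimated correlation). ODF1 was at -4.72 (SE 0.42), OAZ3, the testis antizyme gene, at -4.39 (SE 0.50) and SPATA18 at -2.26 (SE 0.45). FSIP2, at 1.76 (SE 0.35), and TEKT5, at 1.58 (SE 0.21), were higher. The transition protein genes, which act between histones and protamines in spermatid DNA packing, went opposite ways: TNP1 was higher at 3.19 (SE 0.49) and TNP2 lower at -6.13 (SE 0.47). The chromatin list as a whole was not called by camera, with 2 higher and 1 lower of 6 (adjusted p = 0.50). Nor were acrosome genes (5 higher and 1 lower of 15, adjusted p = 0.886), sperm-egg interaction genes (2 higher and 2 lower of 9, adjusted p = 0.457) or ion channels (3 higher and 1 lower of 12, adjusted p = 0.821). The same held for energy metabolism (4 higher and 6 lower of 16, adjusted p = 0.387) and for kinases and phosphatases (2 higher and 2 lower of 13, adjusted p = 0.387). Other spermatid-expressed genes (5 higher and 3 lower of 22, adjusted p = 0.503) and heat shock and chaperonin genes (5 higher and 6 lower of 26, adjusted p = 0.22) were not called either. Of these 8 lists fry called 2, acrosome genes (adjusted p = 0.00451) and ion channels (adjusted p = 0.0329). Among their members, the sperm glycolysis genes PGK2, at -3.80 (SE 0.49), and GAPDHS, at -3.28 (SE 0.43), were lower, as was the spermatid kinase gene TSSK6, at -2.98 (SE 0.48). The hyaluronidase gene SPAM1, at 2.02 (SE 0.15), and SPACA4, at 2.39 (SE 0.43), were higher.

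The limma test called 4615 of 9251 genes, 3172 higher and 1443 lower in human. The libraries of the species did not overlap in 5136 of the 9251 genes, 55.5%, where chance gives 0.433%, and 4140 of these were called. Median-of-ratios scaling gave 1925 higher and 2342 lower, and quantile normalization gave 2233 higher and 2061 lower, so the balance of directions depended on the scaling. Of the called genes, 587 had values in multiples of a different number of reads in the 2 species. Such genes were called more often than others, 57.4% against 48.9%.

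Of the outer dense fibre and fibrous sheath genes 13 of 17 tested, and of other spermatid-expressed genes 12 of 22, were lower in human than in rat sperm. OAZ3 stood at 12.5 ± 4.29 TPM in human (mean ± SD, n = 6) and 39082 ± 28159 in rat (n = 7), a log2 change of -11.43 (SE 0.46). ODF1, the major protein gene of the outer dense fibres, stood at 0.656 ± 0.435 and 533 ± 226 TPM. TNP2 stood at 9.02 ± 4.89 and 3546 ± 1636, and HSPB9, a testis small heat shock protein gene, at 4.14 ± 1.38 and 3391 ± 2347. TNP1 did not follow: it stood at 909 ± 641 TPM in human and 929 ± 370.4 in rat and was not called. The median gene was 0.22 higher in human, and changes are relative to it.

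The other genes lowest in human were SERPINA1 at -9.49 (SE 0.43), the antitrypsin gene, KRT20 at -9.33 (SE 1.02), a keratin gene, LENG8 at -9.10 (SE 1.03), TNP2 at -8.62 (SE 0.43) and ODF1 at -8.40 (SE 0.38). Then came HBA2 at -7.98 (SE 0.81), an alpha globin gene, AZIN2 at -7.76 (SE 0.42), an antizyme inhibitor gene, and MT-CO1 at -7.16 (SE 0.92), with HSPB9 at -9.31 (SE 0.44). KRT20 rested on 0 to 1 reads per human and 3 to 25 per rat library. The genes highest in human were CSN3 at 6.87 (SE 1.26), the kappa casein gene, FGD1 at 6.22 (SE 0.46), TAAR5 at 6.22 (SE 1.65), and BAG5 at 5.99 (SE 0.35), a co-chaperone gene. They were followed by CRYGA at 5.71 (SE 0.30), a lens crystallin gene, OTP at 5.63 (SE 0.82), a homeobox gene, ZNF195 at 5.48 (SE 0.39), a zinc finger gene, GPR35 at 5.18 (SE 0.60) and TCEANC at 5.18 (SE 0.38). These rested on few rat reads, 0 to 2 of CSN3 and 0 to 9 of BAG5 per library, and CSN3 had only 5 to 10 in human. TAAR5 had 0 TPM in rat 15 and rat 24 and 861 to 4744 in the other rat libraries. Its rat mean was 1487 TPM, and 944 without rat 22, so its large log2 change rested in part on the libraries at 0. Reads of ZNF195 came in multiples of 105 in human and 15 in rat, a ratio of 2.81 on the log2 scale.

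By group, of the outer dense fibre and fibrous sheath genes 2 of 17 tested members were higher and 13 lower (2 and 14 adjusted over the list alone), with a median of -3.89 (adjusted p = 8.16e-07 by camera, adjusted p = 0.594 with an estimated correlation). SPATA18 was at -4.83 (SE 0.42), and FSIP2 was higher at 1.61 (SE 0.33). Of the other spermatid-expressed genes 1 of 22 tested members were higher and 12 lower (median -1.52, adjusted p = 7.20e-05 by camera, adjusted p = 0.594 with an estimated correlation). GGN was at -6.23 (SE 0.38), TPPP2 at -4.65 (SE 0.38) and KLHL10 at -3.60 (SE 0.31). TXNDC2, a sperm thioredoxin gene, was higher at 2.21 (SE 0.32). Of the kinase and phosphatase genes 2 of 13 tested members were higher and 7 lower (median -1.24, adjusted p = 0.012 by camera, adjusted p = 0.594 with an estimated correlation). TSSK6 stood at 38.5 ± 14.1 TPM in human and 2143 ± 1489 in rat (-5.78, SE 0.44). PHKG2, a phosphorylase kinase gene, was at -4.65 (SE 0.38), and STK33 was higher at 1.49 (SE 0.14). For mitochondrially encoded proteins 0 of 13 tested members were higher and 9 lower (median -3.99, adjusted p = 0.00272 by camera, adjusted p = 0.77 with an estimated correlation). MT-CO3 was at -6.57 (SE 0.89). Rat libraries differed widely, with mitochondrial shares of TPM from 0.0135% in rat 22 to 2.91% in rat 24. The list of mitochondrially encoded proteins stayed called by camera without either of them. Nuclear-encoded oxidative phosphorylation had 3 higher and 18 lower of 37 (median -1.10, adjusted p = 0.00272 by camera, adjusted p = 0.77 with an estimated correlation). NDUFV2 was at -4.91 (SE 0.62) and COX8A at -4.43 (SE 0.62). Ribosomal protein genes had 5 higher and 15 lower of 42 (median -0.62, adjusted p = 0.0145 by camera, adjusted p = 0.77 with an estimated correlation). RPS15 at -6.93 (SE 0.38) was the lowest and RPS26 at 1.67 (SE 0.24) the highest. The list missed the threshold without rat 24 (adjusted p = 0.0501).

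The remaining groups were not called as lists by camera, whose adjusted p follows, while fry called 9 of 10, such as energy metabolism (adjusted p = 0.000129). Acrosome genes had 2 higher and 8 lower of 15 (adjusted p = 0.0798), with ACTL7A at -4.14 (SE 0.44) and ACTRT2 at -3.40 (SE 0.35), both actin-related, and SPAM1 higher at 2.05 (SE 0.13). Energy metabolism had 2 higher and 6 lower of 16 (adjusted p = 0.149), and its members GAPDHS and PGK2 were lower in human. GAPDHS stood at 0.253 ± 0.15 TPM against 132 ± 111 in rat, and PGK2 at 6.43 ± 5.02 against 546 ± 265. The chromatin list had 2 higher and 3 lower of 6 (adjusted p = 0.171), with TNP2 and PRM3 (-4.10, SE 0.36) lower. Axoneme genes had 13 higher and 3 lower of 35 (adjusted p = 0.171), with DNAH3 at 2.73 (SE 0.20) and CCDC40 at 2.16 (SE 0.27) higher. Sperm-egg interaction had 0 higher and 2 lower of 9 (adjusted p = 0.153), CRISP2 at -2.87 (SE 0.41) and CALR3 at -2.37 (SE 0.26). Ion channels had 0 higher and 1 lower of 12 (adjusted p = 0.572), heat shock and chaperonin genes 2 higher and 7 lower of 26 (adjusted p = 0.0698) and proteasome genes 2 higher and 8 lower of 28 (adjusted p = 0.0608). Housekeeping genes had 1 higher and 5 lower of 12 (adjusted p = 0.171), with B2M at -3.80 (SE 0.81). Rat 19, rat 21 and rat 22 held 1.06 to 6.65 TPM of B2M and the other rat libraries 47.5 to 113. Epididymal epithelium markers had 2 higher and 6 lower of 18 (0 and 6 adjusted over the list alone, list adjusted p = 0.0924), SPINK8 at -4.84 (SE 0.72) and LCN12 at -4.0 (SE 0.38) among the lower ones.

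The limma test called 4366 of 9251 genes, 2551 higher and 1815 lower in human. The libraries of the species did not overlap in 3485 of the 9251 genes, 37.7%, where chance gives 0.117%, and 3092 of these were called. Median-of-ratios scaling gave 1850 higher and 2212 lower. Rescaling without the genes of divisor up to 10, chosen after the data were seen, gave 6204 higher and 2772 lower among genes filtered anew. Of the called genes, 640 had values in multiples of a different number of reads in the 2 species. Such genes were called more often than others, 62.1% against 45.3%.

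Between the rodents, both sampled from the cauda epididymis, 29 of 42 ribosomal protein genes and 14 of 18 epididymal markers tested were higher in mouse, with 3 and 2 lower. Lower in mouse were 16 of 22 other spermatid-expressed genes and 12 of 17 genes of the outer dense fibre and fibrous sheath. RPS6 stood at 341 ± 194 TPM in mouse (mean ± SD, n = 5) and 5.86 ± 5.0 in rat (n = 7), a log2 change of 6.04 (SE 0.52). SPINK8 stood at 5850.2 ± 6476 and 133 ± 112, its mouse mean being 3001 without mouse 3. Rat libraries were not alike in it: rat 19, rat 21 and rat 22 held 17.5 to 55.5 TPM and the others 96.6 to 279. OAZ3 went the other way, at 196 ± 46.8 TPM in mouse and 39082 ± 28159 in rat (-7.05, SE 0.48), as did SERPINA1, at 0.322 ± 0.194 and 1287 ± 856 (-9.37, SE 0.45). The median gene was lower in mouse by a log2 change of -0.28, and changes are relative to it.

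The genes highest in mouse were ARID4B at 6.14 (SE 0.24), a chromatin regulator gene, the protease inhibitor genes SPINK5 at 6.14 (SE 0.23), SPINK6 at 6.06 (SE 0.44) and SPINK8 at 5.75 (SE 0.75), and RPS6 at 6.04 (SE 0.52). They were followed by BAG5 at 5.83 (SE 0.37), ELOB at 5.73 (SE 0.38), an elongin gene, GPX3 at 5.53 (SE 0.48), CUZD1 at 5.51 (SE 0.38) and RBM39 at 5.48 (SE 0.34), a splicing factor gene. Rat libraries held 0 to 4 reads of SPINK5 and 0 to 1 of SPINK6, and mouse values of both came in multiples of 4 and 3 reads. The genes lowest in mouse, after SERPINA1 and OAZ3, were PHOSPHO1 at -7.35 (SE 0.41), a phosphatase gene, TAS1R2 at -5.89 (SE 0.32), a sweet taste receptor gene, FAM161A at -5.64 (SE 0.38), JMJD7-PLA2G4B at -5.22 (SE 0.55) and HSPB9 at -5.14 (SE 0.46). TCP10L2 was at -7.21 (SE 0.46), TCP10L at -6.16 (SE 0.35) and TCP10L3 at -5.60 (SE 0.34). The TCP10L genes carried the same rodent reads, 137 to 368 per mouse and 1599 to 35352 per rat library, and count as 1 observation.

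By group, of the ribosomal protein genes 29 of 42 tested members were higher and 3 lower (30 and 3 adjusted over the list alone, median 2.33, adjusted p = 2.51e-14 by camera, adjusted p = 0.594 with an estimated correlation). RPS20 was at 5.0 (SE 0.33), RPS26 at 4.72 (SE 0.26) and RPL13 at 3.90 (SE 0.43), with RPS15, at -1.78 (SE 0.40), among the lower. Of the epididymal epithelium markers 14 of 18 tested members were higher and 2 lower (median 2.40, adjusted p = 0.000103 by camera, adjusted p = 0.594 with an estimated correlation). CLU was at 3.94 (SE 0.43) and CES5A at 2.93 (SE 0.74), whereas PATE4, at -3.32 (SE 0.55), and CUBN, at -2.54 (SE 0.54), were lower. Of the other spermatid-expressed genes 0 of 22 tested members were higher and 16 lower (median -1.43, adjusted p = 2.79e-06 by camera, adjusted p = 0.594 with an estimated correlation). TPPP2 was at -2.77 (SE 0.40) and SUN5, which couples the sperm head to the tail, at -2.50 (SE 0.45). Of the outer dense fibre and fibrous sheath genes 0 of 17 tested members were higher and 12 lower (median -2.41, adjusted p = 5.09e-05 by camera, adjusted p = 0.729 with an estimated correlation). ODF1 was at -3.69 (SE 0.40) and SPATA18 at -2.57 (SE 0.44). Of the acrosome genes 1 of 15 tested members were higher and 8 lower (median -0.85, adjusted p = 0.00472 by camera, adjusted p = 0.77 with an estimated correlation). CYLC1 was at -4.36 (SE 0.44) and ACTL7A at -3.26 (SE 0.46). Of the kinase and phosphatase genes 0 of 13 tested members were higher and 6 lower (median -0.42, adjusted p = 0.00616 by camera, adjusted p = 0.594 with an estimated correlation). TSSK6 was at -2.80 (SE 0.46), PHKG2 at -3.53 (SE 0.40) and TSSK3 at -2.64 (SE 0.33).

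Among the lists not called by camera, of which fry called 6 of 10, chromatin packaging had 1 higher and 4 lower of 6 (adjusted p = 0.227). TNP1 was lower in mouse at -3.55 (SE 0.48), PRM3 at -3.46 (SE 0.38) and TNP2 at -2.49 (SE 0.46), while PRM2 was higher at 2.0 (SE 0.43). Energy metabolism had 2 higher and 5 lower of 16 (adjusted p = 0.248). GAPDHS, at -3.32 (SE 0.41), and PGK2, at -2.70 (SE 0.48), were lower, and LDHC, the sperm lactate dehydrogenase gene, at 2.03 (SE 0.31), and SORD, the sorbitol dehydrogenase gene, at 1.60 (SE 0.21), were higher. Ion channels had 1 higher and 2 lower of 12 (adjusted p = 0.387), with CATSPERG, a subunit gene of the sperm calcium channel, at -3.06 (SE 0.34) and ATP2B4, a calcium pump gene, at 2.02 (SE 0.26). Axoneme genes had 1 higher and 14 lower of 35 (adjusted p = 0.129), with DNAH12 at -2.29 (SE 0.28). Sperm-egg interaction had 1 higher and 5 lower of 9 (adjusted p = 0.462), with PDILT at -2.07 (SE 0.44) and IZUMO4 at 1.82 (SE 0.25). Heat shock and chaperonin genes had 4 higher and 6 lower of 26 (adjusted p = 0.572), with HSPA8 at 3.33 (SE 0.41) and HSPA4L at -2.93 (SE 0.31). Proteasome genes had 1 higher and 4 lower of 28 (adjusted p = 0.443), oxidative phosphorylation 4 higher and 3 lower of 37 (adjusted p = 0.251), mitochondrially encoded proteins 0 higher and 6 lower of 13 (adjusted p = 0.372) and housekeeping genes 3 higher and 3 lower of 12 (adjusted p = 0.367). Without mouse 3 the housekeeping genes B2M (limma adjusted p = 0.0698) and EEF2 (adjusted p = 0.0523), both higher in mouse, lost their calls.

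The limma test called 3029 of 9251 genes, 1023 higher and 2006 lower in mouse. The libraries of the species did not overlap in 2031 of the 9251 genes, 22%, where chance gives 0.253%, and 1679 of these were called. Median-of-ratios scaling gave 1644 higher and 1493 lower and quantile normalization 1484 higher and 1500 lower. Recovered reads gave 3697 higher and 3480 lower among genes filtered anew. Of the called genes, 576 had values in multiples of a different number of reads in the 2 species. Such genes were called more often than others, 45.4% against 30.7%. Across the 3 comparisons, counts adjusted over the list alone equalled those over all genes tested wherever no other count is given. Where a list has 0 members in a direction, limma at an unadjusted p under 0.05 and the same size of change gave 0 to 1, counting also the lists of other cell types. None of the 20 list calls held with an estimated correlation between genes, by camera, with 5 lists at an unadjusted p under 0.05, while fry called 44. In 54 of 100 splits of the libraries into groups of the same sizes, camera called as many lists. All 20 called medians kept their sign after quantile normalization and on recovered reads, but their sizes moved. On recovered reads the unshifted median of the outer dense fibre list between human and mouse went from -1.10 to -2.61, and that of ribosomal protein genes between human and rat from -0.40 to -0.15.

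**Figure D3:**
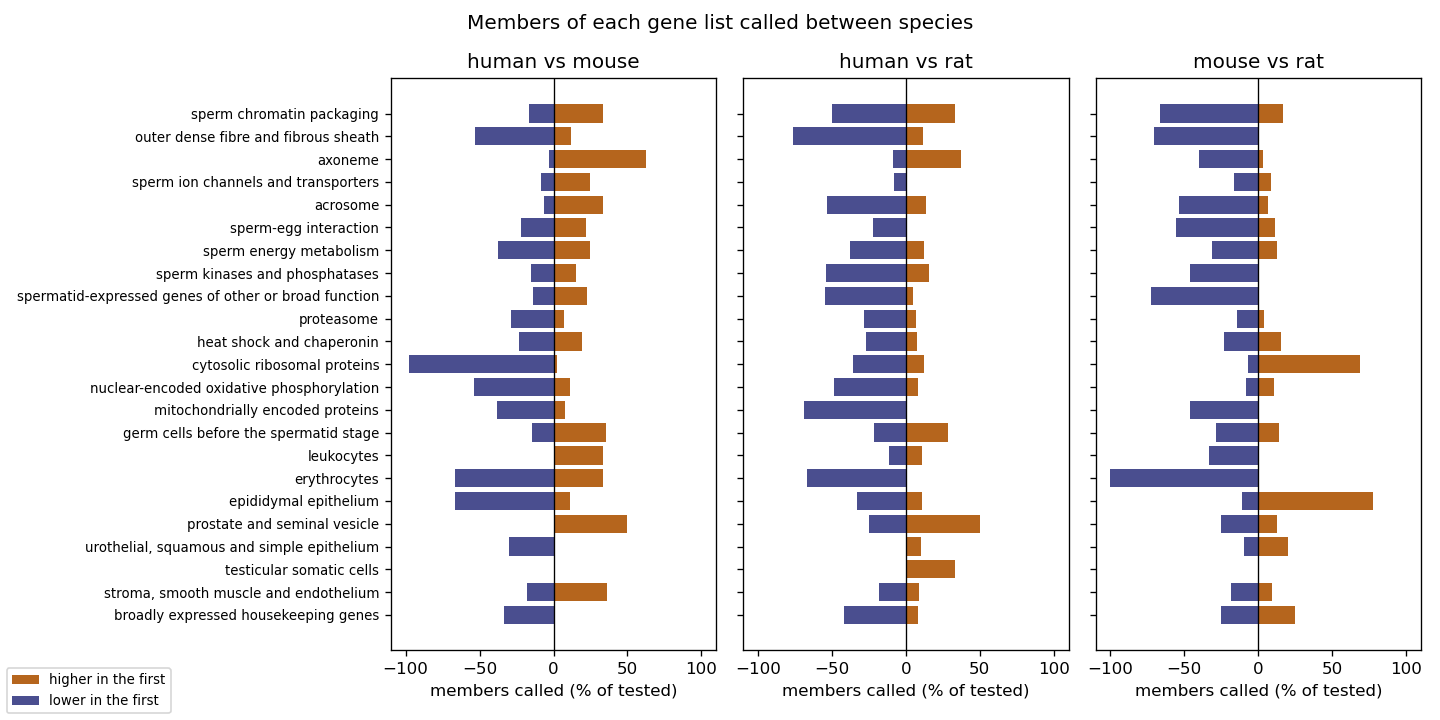
Share of the tested members of each gene list called higher (right) or lower (left) in the first species named, in percent, one panel per species pair and one bar each way per list. Ribosomal protein genes were lower in human than in mouse in 41 of 42 cases and higher in mouse than in rat in 29.

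**Figure D4:**
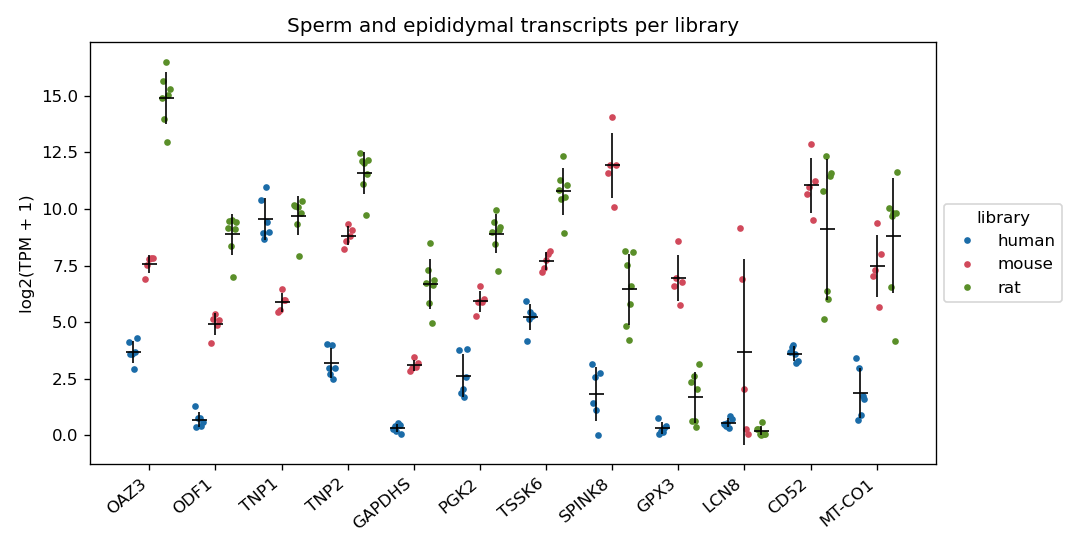
Abundance of 12 transcripts as log2(TPM + 1), one point per library, with dashes and bars for the mean and SD per species (human n = 6, mouse n = 5, rat n = 7). OAZ3, ODF1, GAPDHS and TSSK6 rise from human to mouse to rat, whereas TNP1 is lowest in mouse.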

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

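The search for libraries apart from the rest of their group was fixed beforehand for library and list measures, while the genes whose levels are given were chosen after the data were seen. No explanation was tested here. A library was singled out where its gap to the nearest other library of its species was large against the range of the species (Dixon's criterion). Chance singles out about 1 in 20 groups where values are normally distributed, and can single out more where they are skewed, as TPM can be. Here 21 of 159 groups were singled out, which cannot be set against that rate. Setting these side by side is not a test, since genes were picked after the data were seen and some measures share genes.

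Rat 24 stood apart in its mitochondrial share of TPM, 2.91% against 0.0135% to 1.04% in the other rat libraries, and in MT-CO1, 3218 TPM against 16.9 to 1056, and MT-CO3, 2778 TPM against 16.2 to 1026. It had the fewest genes above 0, 15985 against 17275 to 18242, and the lowest median rho to the other rat libraries over all 53785 rows with human IDs, 0.929 against 0.953 to 0.965. Its leukocyte markers had the highest median percentile, 70.4 against 40.5 to 53.1. Rat 22 had the lowest median percentile of chromatin packaging genes, 88.2 against 95.7 to 97.8, and of other spermatid-expressed genes, 60.9 against 73.2 to 81.9. Its mitochondrially encoded proteins were lowest too, 72.4 against 92.4 to 99.6, and it had the highest LCN8, 0.485 TPM against 0.0187 to 0.217. Rat 21 was highest in kinase and phosphatase genes (median percentile 77.1 against 59.2 to 66.1), in TSSK6 (5198 TPM against 488 to 2486) and in GAPDHS (366 TPM against 30.1 to 156).

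Mouse 3 was highest in the epididymal and secretory transcripts SPINK8 (17249 TPM against 1089 to 3914 in the other mouse libraries), CD52 (7394 against 722 to 2381) and GPX3 (380.2 against 53.3 to 123), and in MT-CO3 (98 against 5.48 to 29). Mouse 1 was highest in the epididymal lipocalin transcript LCN8, 567 TPM against 0.0409 to 119.9. Human 7 was highest in ODF1, 1.47 TPM against 0.266 to 0.705 in the other human libraries, and lowest in SYCP3, 4534 against 6141 to 7016. It had the lowest share of TPM in its 10 genes of highest TPM, 27.3% against 30.3% to 31.5%.

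The rows of the table on mouse gene IDs, which no comparison uses, held 21397 to 81470 TPM per mouse library.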

How the results depend on the processing

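The tests on recovered reads, common factors and divisors, and the one without rat 22 and rat 24, were chosen after the data were seen. No call of a named gene and none of the 20 list calls by camera reversed its direction, but the balance of called genes did. Among lists not called, camera and fry pointed opposite ways in some, such as kinases and phosphatases between human and mouse. Under median-of-ratios scaling it was 1925 higher and 2342 lower between human and mouse, 1850 higher and 2212 lower between human and rat and 1644 higher and 1493 lower between mouse and rat. No paired analysis was possible because the only replicate number shared by 2 species, 19 in human and rat, joins different individuals of different species.

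Counts of genes differing are given for human and mouse, human and rat, and mouse and rat in turn (4615, 4366 and 3029 as reported). They were 1932, 1839 and 1282 with a pseudocount of 5, 1956, 1915 and 1519 with a mean of at least 5 TPM, which tests fewer genes, and 2344, 2196 and 991 with limma's treat against a log2 change of 1. On recovered reads, and in the rescaling without small divisors, the filter on low means was applied anew. The genes tested then differed from the 9251, so the next counts do not compare directly with those above. Recovered reads, scaled to the library total, gave 10100, 10265 and 7177, the same with median-of-ratios scaling 9915, 9694 and 7676, without common factors 8353, 8453 and 5766 and without mitochondrial genes 10111, 10139 and 7261. Rescaling without genes of divisor up to 10 gave 8924, 8976 and 6120. The cause was not tested. Mouse against rat, the calls split into 3711 higher and 2409 lower under that rescaling. They split into 3628 higher and 4048 lower, 2888 higher and 2878 lower and 3438 higher and 3823 lower on recovered reads with median-of-ratios scaling, without common factors and without mitochondrial genes. Human against mouse, recovered reads with median-of-ratios scaling gave 4977 higher and 4938 lower. Leaving out 1 library gave 4455 to 4657, 4277 to 4622 and 2859 to 3326.

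The count of similar genes (52) was 4828 with a pseudocount of 5, 5306 with no mean filter, 1 with the same total over the paired genes, 374 after median-of-ratios scaling and 423 after quantile normalization. It was 84 without families of shared reads, 78 among genes with no common factor, 4328 with a bound of 2 and 222 without rat 22 and rat 24. With 1 library left out it was 15 to 254, highest without rat 22. By limma it was 0 with a pseudocount of 0.1 (180 at an unadjusted p under 0.05), with a mean of at least 5 TPM (76). It was 0 too on recovered reads (235), these with median-of-ratios scaling (359), without common factors (215) or mitochondrial genes (255), and after rescaling without divisors up to 10 (490). The count thus depended on the added value and on genes of low TPM, whose differences the added value shrinks. No other cause was tested.

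Detected genes (10699 human, 4855 mouse, 4115 rat and 2133 in all 3) came to 36079, 21580, 15069 and 12708 at any value above 0, 3331, 1597, 1330 and 595 at 5 TPM and 19426, 15562, 11024 and 7508 at 10 recovered reads. In at least 0.5 of the libraries of a species, 7722 were detected in mouse, 8140 in rat and 4223 in all 3. With 1 library left out they were 10825 to 11548, 4906 to 5741, 4143 to 4674 and 2136 to 2307. Rank correlations were 0.365, 0.336 and 0.601 on recovered reads and 0.343, 0.317 and 0.613 without common factors, since the divisors are shared, and 0.546 to 0.563, 0.557 to 0.577 and 0.704 to 0.728 with 1 library left out.

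Camera called 20 list tests, 0 with an estimated correlation (5 at an unadjusted p under 0.05), 44 by fry and 19 to 25 with 1 library left out. For the named genes, 11523 values kept their direction and side of the threshold, and 581 fell short of it in the same direction. For lists the numbers were 469 and 31. For genes of similar abundance 129 held and 199 did not. Depth limits genes near the floor, since 1 read in a gene of divisor 1 is worth 26.6 to 249.7 TPM, depending on the library.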

Other observations

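The lists of other cell types are reported as values. Camera called none of their 21 tests, and fry, which tests against no change, called 8. Among these, prostate and seminal vesicle markers had adjusted p = 2.68e-06 between human and mouse and erythrocyte markers adjusted p = 1.96e-06 between human and rat. List p-values below are those of camera. Leukocyte markers had 3 higher and 0 lower of 9 (adjusted p = 0.821) between human and mouse, 1 higher and 1 lower of 9 (adjusted p = 0.478) between human and rat, and 0 higher and 3 lower of 9 (adjusted p = 0.277) between mouse and rat. The integrin gene ITGAM was lower in mouse than in rat at -2.58 (SE 0.47), and PTPRC, the leukocyte common antigen gene, was higher in human than in mouse at 1.33 (SE 0.24). Erythrocyte markers had 1 higher and 2 lower of 3 (adjusted p = 0.467), 0 higher and 2 lower of 3 (adjusted p = 0.153) and 0 higher and 3 lower of 3 (adjusted p = 0.171) in the same order. The call of HBA1 between human and mouse was lost without single libraries of either species. Its limma adjusted p was then 0.0514 (without human 12) to 0.0916 (without mouse 1). HBA2 was lower in human than in rat at -7.98 (SE 0.81). Prostate and seminal vesicle markers had 4 higher and 0 lower of 8 (adjusted p = 0.387), 4 higher and 2 lower of 8 (adjusted p = 0.489) and 1 higher and 2 lower of 8 (adjusted p = 0.886). The prostate gene FOLH1 was higher in human than in mouse at 1.42 (SE 0.18). Epithelial markers had 0 higher and 3 lower of 10 (adjusted p = 0.149), 1 higher and 0 lower of 10 (adjusted p = 0.48) and 2 higher and 1 lower of 10 (adjusted p = 0.171). The keratin genes KRT19 and KRT18 were higher in mouse than in rat at 2.67 (SE 0.34) and 1.69 (SE 0.25). Testicular somatic markers had 0 higher and 0 lower of 3 (adjusted p = 0.957), 1 higher and 0 lower of 3 (adjusted p = 0.848) and 0 higher and 0 lower of 3 (adjusted p = 0.593). Stromal markers had 4 higher and 2 lower of 11 (4 and 1 adjusted over the list alone, list adjusted p = 0.67), 1 higher and 2 lower of 11 (adjusted p = 0.462) and 1 higher and 2 lower of 11 (adjusted p = 0.84), and SPARC was lower in human than in mouse at -3.33 (SE 0.61). Germ cells before the spermatid stage had 5 higher and 2 lower of 14 (adjusted p = 0.485), 4 higher and 3 lower of 14 (adjusted p = 0.997) and 2 higher and 4 lower of 14 (adjusted p = 0.344). The meiosis gene HORMAD2 was higher in human than in mouse at 1.89 (SE 0.29).

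The median and the mean of a list's unshifted log2 changes differed in sign for several lists. Between human and mouse these were acrosome genes (-0.08 and 0.57), sperm-egg interaction (-0.03 and 0.09), energy metabolism (0.41 and -0.29), heat shock and chaperonin genes (0.24 and -0.29) and epithelial markers (0.08 and -0.49). Between human and rat it was energy metabolism (0.04 and -1.12), and between mouse and rat the proteasome (0.03 and -0.09) and oxidative phosphorylation (-0.01 and 0.14). Camera, which compares a list with all other genes, pointed against both for other spermatid-expressed genes and testicular somatic markers between human and mouse (0.17 and 0.23, and 0.15 and 0.26) and for prostate markers between mouse and rat (-0.04 and -0.41). None of these lists was called by camera. Fry called acrosome genes between human and mouse (adjusted p = 0.00451) and energy metabolism between human and rat (adjusted p = 0.000129).

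The tests of splits of the gene counts, of divisors against gene length, of gene span, of depth and of the epididymal list were chosen after the result was seen. Other splits of the libraries into groups of the same sizes, 100 in each case with the real one among them, were compared with the real groups. The real groups gave the largest count in each pair. These were 4615 genes between human and mouse (1 split as large, the highest other 3867), 4366 between human and rat (1, the highest other 3150) and 3029 between mouse and rat (1, the highest other 1742). Groups that mix species spread more widely and tend to give fewer calls, so these splits do not exclude chance. For the 52 similar genes the splits decide nothing, because groups that mix species spread more widely. By limma the other splits gave at most 0, and up to 3225 at an unadjusted p under 0.05 against 905 for the real groups. Chance was not excluded for the 20 list calls, since 54 of 100 splits gave as many and the highest other gave 39. A random split can still set mostly 1 species against another, so these counts are not those of alike samples.

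The divisors of the deposited values had no relation to annotated exon length (rho 0.00880 across 18282 genes), which argues against gene lengths on the right genes. A candidate explanation is that lengths were sorted as text before they were joined to genes. The rho of the divisors with the text order of each gene's own exon length was -0.00233 across 39280 genes. The largest rho among 8 orderings tried was 0.0132 in size. These values cannot decide the question, because lengths joined to other genes need not follow a gene's own length. The authors' annotation is not known either, and other lengths would have another text order. What the divisors are stays open. No biological explanation was tested.

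Libraries held reads of olfactory receptor genes. Of 260 such genes, 243 had a mean of at least 1 recovered read in human, 225 in mouse and 218 in rat. The 260 were taken from genes above 0 in at least 1 library of each species. That selection in part makes the counts alike, so they cannot show whether the species are alike. The median receptor gene had a mean of 10.2 reads per library in human, 7.1 in mouse and 4.07 in rat, and reads of some genes come in multiples. Neither the counts nor these means were scaled to the reads of a library, and the human libraries had the lowest median of recovered reads. Greater depth is argued against, since the median human library held 0.652 of the reads of the lower rodent median. Unspliced or genomic RNA might explain the higher human reads. The partial rho of reads and gene span, with exon length fixed, was 0.183 in human, -0.0118 in mouse and -0.0367 in rat, which decides for neither side. The bound set for that explanation was 0.2 and the one against it 0.1, so it cannot be told apart from other explanations. Human transcription of these genes, the species difference that the design holds, stays open and untested.

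Of the 18 epididymal markers tested, 14 were higher and 2 lower in mouse than in rat libraries (adjusted p = 0.000103 by camera, adjusted p = 0.594 with an estimated correlation). RNA from epididymal epithelium may be carried with the mouse sperm. The median change of these markers lay at percentile 100 of 10000 random lists matched on expression, which restates the difference. It does not part carried-over epithelium from a species difference, so the 2 cannot be told apart. Examples are SPINK8 (5850.2 ± 6476 TPM in mouse, 133 ± 112 in rat, mean ± SD, n = 5 and 7) and LCN8 (138 ± 245 and 0.151 ± 0.169). Without mouse 3 the mouse mean of SPINK8 was 3001 TPM. That of LCN8 was 30.8 without mouse 1, and 2 of the 5 mouse libraries had no more LCN8 than rat 22. Without rat 22 the rat mean of LCN8 was 0.0959 TPM. Of these markers 0 stand in another list, and 9 had a mean of at least 1 TPM in human and 13 in rat. CD52, which is outside this list, was not particular to mouse, whose libraries held 722 to 7394 TPM of it. Rat 15, rat 20, rat 23 and rat 24 held 1770 to 5146 TPM of CD52, and rat 19, rat 21 and rat 22 held 34.2 to 81.0. The same libraries parted in SPINK8 (96.6 to 279 against 17.5 to 55.5 TPM), GPX3 (3.16 to 7.79 against 0.266 to 0.561) and B2M (47.5 to 113 against 1.06 to 6.65). The median percentile of ribosomal protein genes parted too, 84.6 to 93.0 against 59.4 to 79.6, but LCN8 and RPS6 did not. Rat means of the genes that parted thus join unlike libraries. Every mouse library held more SPINK8 and GPX3 than any rat library. Leukocytes carried over more in mouse than in rat are argued against only by the 9 of 24 leukocyte markers tested, whose median lay at percentile 12.3. Rat 24 had a leukocyte median percentile of 70.4, against 40.5 to 53.1 in the other rat libraries. It may lower that value, and the test was not run without it. The test takes mouse minus rat, so it does not show whether libraries of either species held leukocyte RNA. A species difference in the sperm or the epididymis, and the way each cauda was sampled, stay open and were not tested.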
